A study of Mus musculus with 6 samples.

How the data were processed

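RNA was sequenced from the inguinal white adipose tissue of mice kept at 4 °C for 6 hours. The 6 libraries fell into 2 groups of 3 by their genotype label: mice with an adipocyte-specific knockout of Celf1 (Celf1 AKO) and floxed controls (Flox control), numbered 1 to 3 within each group. The labels do not say in so many words that each library came from a different mouse, so the p-values measure the spread between these libraries. Per the labels' protocols, total RNA was extracted with Trizol, and mRNA was isolated, fragmented, copied into cDNA, ligated to adaptors, amplified and circularized before sequencing. The submitters' processing notes name HISAT2, RSEM 1.3.1 and the mouse builds GRCm38 and mm10, without saying what each was used for. The annotation, the strand setting and the rule by which genes entered the table are not given in the sources used here, so antisense and overlapping genes cannot be told apart by strand.

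The authors deposited whole-number read counts per Ensembl gene, not normalized, for 16627 genes, and per the file headers each column is 1 library. The authors also deposited FPKM values for the same genes and libraries. Tested on the values, each FPKM was the count divided by 1 fixed length per gene and 1 factor per library. In Celf1 AKO replicate 3 that factor was 0.982% larger than the library's total in the count table, relative to Flox control replicate 3, and in the other libraries it lay within 0.0294% of it. Every gene in the table had a total of at least 53 counts over the 6 libraries. Gene names, positions and biotypes came from GENCODE M21, which is on GRCm38: 16528 identifiers matched and 99 did not. No 2 libraries agreed within sampling noise: the chi-square of their counts over its degrees of freedom was at least 48.4 for every pair.

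Library totals ran from 54835348 to 64979443 counts, so a gene at 1 CPM (read counts scaled to library size and the TMM factor) rested on about 54.9 to 67.8 counts per library. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM normalization, the default expression filter (16366 genes tested, 261 removed) and robust estimation of the spread, on all 6 libraries with genotype as the only term. Benjamini-Hochberg adjusted p-values under 0.05 were called. CPM values are scaled by the TMM factors, errors of CPM are SDs over 3 libraries, and standard errors (SE) of log2 fold changes were taken as the fold change over the root of the test's F statistic. On counts simulated for the tested genes with their measured spread, of which 16198 passed the filter again, this test called 10% of genes changed 1.5-fold, 60% of genes changed 2-fold, 96% of genes changed 4-fold and 100% of genes changed 8-fold, with 12 unchanged genes called. DESeq2 1.42.0 on the same simulated counts called 34%, 82%, 98% and 100%, with 72 unchanged genes called. Each fold was given to 50 genes. Among DESeq2's calls the share of unchanged genes was thus well above the 0.05 aimed at, and higher than for edgeR. The changed genes were drawn only from genes above a minimum mean CPM, so these rates do not cover genes at low CPM. No library that stands apart from its group was simulated.

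Before the data were examined, 35 gene lists were fixed: pathways of cold-exposed fat, markers of cell types that inguinal fat can hold, skeletal muscle and skin markers, sex-linked genes and control genes. Of the lists' genes, 55 entries were not among the genes analysed here. The 32 lists with at least 5 tested members, leaving out the sex-linked one, were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists. On counts simulated for each gene independently, camera called a list of genes shifted together and 0 of 100 unshifted lists. That simulation cannot show how often camera wrongly calls lists of correlated genes. Estimated correlations here were far above the preset for some lists, such as 0.865 for the nuclear-encoded respiratory chain. A list's score in a library is the mean log2(CPM + 0.5) of its tested members. The rule for naming genes, also fixed before the data were examined, took Celf1, up to 8 called genes per direction with at least 1 CPM and no overlap between the groups, 10 thermogenic and adipocyte genes whatever their test, the 4 members of smallest p in the direction of each called list, up to 3 called members of other lists, and, since fewer than 10 genes passed, the 10 genes of smallest p. Genes named outside it are said to be so, and 2 genes that it takes are not reported here. Single values were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

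Alternatives fixed before the data were examined were RLE, upper-quartile and library-size normalization, 2 other filters, DESeq2, limma-voom with and without quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a minimum of 1 FPKM in 3 libraries and on log2(FPKM + 1) without one, the replicate number as a block, each library left out in turn, and for the lists camera with an estimated correlation and fry. The main edgeR fit was the older (legacy) form, the default in this version; the newer form and a set test after removing a trend with GC content and length were added after seeing the data. Sequence similarity of transcripts was searched with blastn 2.17.0.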

Results

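The series asked what Celf1, an RNA-binding protein that acts on splicing and stability of mRNAs, does in the beiging of inguinal white fat, the appearance of heat-producing adipocytes in the cold. Gene counts were collected from 3 Celf1 AKO and 3 Flox control libraries, all from inguinal fat after 6 hours at 4 °C. The Celf1 AKO libraries held 54835348, 64676854 and 61975868 counts and the Flox control libraries 62382822, 64979443 and 63296387. Across genes, the correlation of log2 CPM between any 2 libraries was at least 0.971, and the libraries did not group by genotype: Celf1 AKO replicate 3 correlated at 0.984 to 0.988 with the 3 controls and at 0.979 and 0.978 with the other 2 knockout libraries. Y-linked genes were present in all 6 libraries, with Ddx3y, named outside the rule, at 198 ± 7.59 CPM in Celf1 AKO and 176 ± 35.3 CPM in Flox control (SD, n = 3 each).

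Celf1 itself (ENSMUSG00000005506; GRCm38 chromosome 2, 90940382 to 91019497, plus strand) was measured at 52.5, 49.8 and 63.0 CPM in Celf1 AKO replicates 1, 2 and 3, and at 126, 114 and 144 CPM in Flox control replicates 1, 2 and 3. The knockout libraries thus held 43.1% of the control level on average, in tissue that also contains cells in which the gene was not deleted, and all 3 lay below all 3 controls. The log2 fold change was -1.21 (SE 0.14), with an adjusted p of 0.122 by edgeR's quasi-likelihood test, which did not pass 0.05, and an exact permutation p of 0.1, the smallest that 3 against 3 allows. Without Celf1 AKO replicate 3 the edgeR adjusted p was 0.0174, and DESeq2 on all 6 libraries gave 2.05e-09. With any other single library left out, the edgeR adjusted p ran from 0.166 (without Celf1 AKO replicate 1) to 0.697 (without Flox control replicate 3).

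In the comparison of all genes, 2 rose in Celf1 AKO and 0 fell. Zfp949, a zinc finger protein gene (ENSMUSG00000032425; chromosome 9, 88548020 to 88571061, plus strand), rose from 9.50 ± 0.56 to 31.9 ± 4.80 CPM (SD, n = 3 each), a log2 fold change of 1.75 (SE 0.15). Gm11868, a processed pseudogene (ENSMUSG00000050550; chromosome 4, 18844202 to 18845679, minus strand), rose from 0.14 ± 0.050 to 2.74 ± 0.18 CPM, a log2 fold change of 4.22 (SE 0.35). It was 98.0% identical to the transcript of Cyb5r4, also named outside the rule, over 1485 aligned bases, so its value is uncertain, as counting could split reads between the 2. Both had an adjusted p of 0.0321 by edgeR. Both missed the threshold without Celf1 AKO replicate 1 (edgeR adjusted p = 0.0860) and without Flox control replicates 1 (0.184 for Gm11868, 0.216 for Zfp949), 2 (0.374) or 3 (0.410), and Gm11868 also without Celf1 AKO replicate 2 (0.0571).

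The other genes of smallest p, Celf1 among them, did not pass the test. Lower in all 3 Celf1 AKO libraries were Mtfp1, which acts in mitochondrial fission (6.20 ± 1.05 against 17.5 ± 0.63 CPM, log2 fold change -1.49), and Pank1, a kinase of coenzyme A synthesis (10.7 ± 1.71 against 33.5 ± 8.90 CPM, -1.65). Higher in all 3 were Hbegf, an EGF-family growth factor (7.50 ± 0.41 against 2.04 ± 0.50 CPM, 1.88), Adamts4, a matrix protease (30.5 ± 4.41 against 8.88 ± 2.75 CPM, 1.78), Akap12, a scaffold of protein kinase A (264 ± 44.2 against 98.2 ± 17.1 CPM, 1.42), Gatm, the first enzyme of creatine synthesis (21.3 ± 3.47 against 9.01 ± 1.14 CPM, 1.24), and Plekhg1 (31.7 ± 3.24 against 15.6 ± 0.89 CPM, 1.02). Their edgeR adjusted p-values ran from 0.122 for Mtfp1 to 0.209 for Gatm, and without Celf1 AKO replicate 3 all 7 passed, from 0.0147 to 0.0312.

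At an unadjusted p under 0.05, edgeR gave 1104 genes higher and 1009 lower among 16366 tested. In CPM, 2836 genes (17.3%) did not overlap between the groups, where the average over all splits of the libraries into 3 and 3 is 10%. Genes are not independent and a single split can lie far from that average, so 17.3% does not by itself show an excess due to genotype. The count of calls moved strongly with the tool and with single libraries. DESeq2 called 342 genes higher and 155 lower, a count that its excess of false calls in the simulation makes uncertain. Leaving out Celf1 AKO replicate 3, edgeR called 237 higher and 290 lower. That library correlated better with each control than the other 2 knockout libraries did, so leaving it out favours a difference. Leaving out Celf1 AKO replicate 1, or any 1 of the Flox control libraries, edgeR called 0. Leaving out Celf1 AKO replicate 2, edgeR called 2, of which 1 was among the 2 named above. Of the genes called by DESeq2 and of those called without Celf1 AKO replicate 3, 194 were shared, all 194 with the same direction. Both fits used the same libraries apart from Celf1 AKO replicate 3, so the shared direction is no independent check.

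Thermogenic genes were at lower counts in Celf1 AKO. Ucp1, the uncoupling protein that makes brown and beige mitochondria produce heat (chromosome 8, 83290352 to 83298452), was at 39.5 ± 37.6 CPM in Celf1 AKO and 508 ± 54.2 CPM in Flox control (SD, n = 3 each), a log2 fold change of -3.69 (SE 0.84). Its 3 knockout values were 79.6, 4.86 and 34.0 CPM, and its 3 control values were 461, 567 and 495 CPM. Dio2, which activates thyroid hormone within the cell, was at 19.2 ± 14.0 against 123 ± 46.6 CPM, and Slc27a2, a fatty acid transporter and acyl-CoA synthetase, at 0.79 ± 0.76 against 7.34 ± 1.79 CPM. Elovl3, a fatty acid elongase of brown fat, was at 3.10 ± 3.12 against 16.0 ± 4.91 CPM. None of these passed the test over all genes by edgeR, with adjusted p-values of 0.246 for Ucp1, 0.251 for Dio2, 0.227 for Slc27a2 and 0.289 for Elovl3. Leaving out Celf1 AKO replicate 3, Elovl3 passed (edgeR adjusted p = 0.0236), but Ucp1 (0.110), Dio2 (0.111) and Slc27a2 (0.0894) did not. DESeq2 on all 6 libraries called Ucp1 (adjusted p = 0.00910), Dio2 (0.0268) and Slc27a2 (9.49e-05) lower, but not Elovl3 (0.101). Given DESeq2's excess of false calls in the simulation, these adjusted p-values may be too small.

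**Figure D1:**
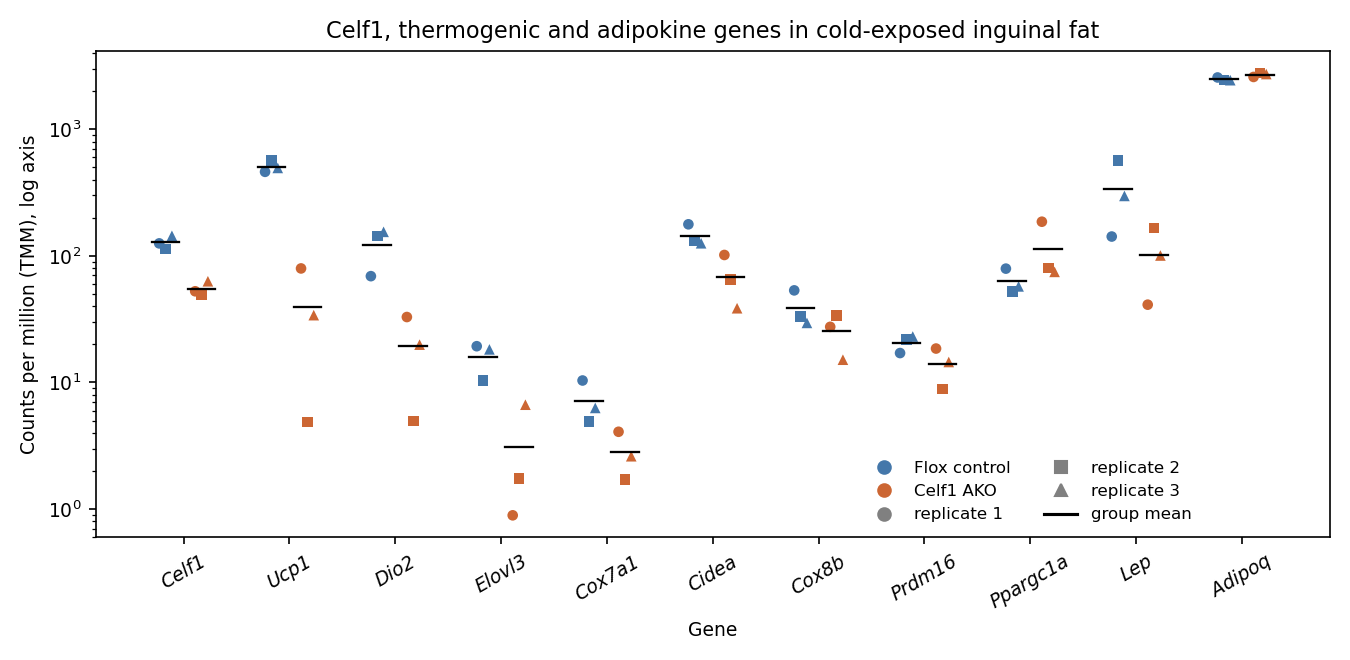
CPM (TMM-scaled read counts, log axis) of Celf1 and of 10 thermogenic or adipocyte genes in the 3 Flox control (blue) and 3 Celf1 AKO (orange) libraries; symbols mark replicates 1 to 3 and black lines the group means. The 3 Celf1 AKO values of Ucp1 (4.86 to 79.6) all lie below the 3 Flox control values (461 to 567), while Adipoq is at similar counts in both groups.

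Of the 28 tested thermogenic and beige genes, 19 had a negative log2 fold change (list median -0.65), 0 passed over all genes, and 12 were lower and 2 higher when adjusted over the list alone. The other always-named members were Cidea (log2 fold change -1.08), the cytochrome oxidase subunits Cox7a1 (-1.36) and Cox8b (-0.60), the beige regulator Prdm16 (-0.56) and the coactivator Ppargc1a (0.85, with edgeR adjusted p of 0.380). Acot11, an acyl-CoA thioesterase, had a log2 fold change of -1.15 (SE 0.18), and Nrg4, a factor secreted by brown fat, was at 79.4 ± 5.09 against 129 ± 13.5 CPM. Their edgeR adjusted p-values were 0.0300 and 0.0352 without Celf1 AKO replicate 3. As a set, the list was lower (camera adjusted p = 1.51e-08). With an estimated correlation the adjusted p was 0.385 and the unadjusted p 0.0162.

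Oxidative metabolism genes lay lower as well. All 19 tested genes of mitochondrial fatty acid oxidation had negative log2 fold changes (median -0.39), 10 of them past the test when adjusted over the list alone and 0 over all genes (camera adjusted p = 5.69e-10; 0.385 with an estimated correlation). Acadm was at 623 ± 32.0 against 998 ± 112 CPM, Etfdh at 197 ± 20.7 against 315 ± 34.1, Acadvl at 208 ± 17.8 against 326 ± 37.7 and Cpt2 at 164 ± 17.8 against 238 ± 9.25. All 14 tricarboxylic acid cycle genes were negative (median -0.31; 6 lower adjusted over the list alone; camera adjusted p = 3.53e-06; 0.446 with an estimated correlation), with log2 fold changes of -0.73 for Idh3a, -0.57 for Sucla2 and -0.43 for Fh1. All 28 nuclear-encoded respiratory chain genes were negative too (median -0.26, and -0.12 with 24 of 28 negative without Flox control replicate 1; 0 adjusted over the list alone; camera adjusted p = 3.52e-06; 0.678 with an estimated correlation), led by Cycs (-0.66), Sdhd (-0.44), Ndufb5 (-0.40) and Uqcrfs1 (-0.40). The 13 mitochondrially encoded genes had a median of -0.03 and were not called (camera adjusted p = 0.545). Without Celf1 AKO replicate 3, Etfdh (edgeR adjusted p = 0.0437), Acadvl (0.0487), Idh3a (0.0307), Cycs (0.0395) and, higher, Gatm (0.0312) passed. The futile creatine and calcium cycling list was higher (5 of 6 tested genes positive, median 0.33, camera adjusted p = 0.0287, 1 gene higher adjusted over the list alone), with log2 fold changes of 1.24 for Gatm, 0.42 for Ckb, 0.23 for Slc6a8 and 0.45 for Gamt. Its 1 tested gene of calcium cycling, Atp2a2, named after its values were seen, was lower in all 3 Celf1 AKO libraries (log2 fold change -0.34). The futile cycling list's camera adjusted p was 0.390 with an estimated correlation, 0.113 with limma-voom, 0.193 with quality weights, 0.0695 to 0.163 in the 3 FPKM fits, 0.125 without Celf1 AKO replicate 3, 0.0563 without Flox control replicate 1 and 0.256 without Flox control replicate 3, where the list's median was 0.15.

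Immediate early and acute cAMP-response genes were higher in Celf1 AKO. All 20 tested had positive log2 fold changes (median 1.45), 13 of them past the test adjusted over the list alone and 0 over all genes (camera adjusted p = 1.14e-15; 0.411 with an estimated correlation). The difference lay mainly in Celf1 AKO replicates 1 and 2, and the list's score was higher in Flox control replicate 1 (0.66 above the control mean) than in Celf1 AKO replicate 3 (0.33). Jun was at 285, 300.4 and 88.3 CPM in Celf1 AKO replicates 1 to 3 and at 86.9, 51.0 and 40.5 CPM in the Flox control ones, and Ier2 at 89.6, 73.5 and 23.2 against 25.4, 15.4 and 14.3 CPM. Atf3 (log2 fold change 1.43, SE 0.33) and Per1 (0.81, SE 0.22) were the other 2 members of smallest p. Without Celf1 AKO replicate 3 the edgeR adjusted p-values of these 4 genes lay between 0.0147 and 0.0281. The list of inflammatory cytokines and chemokines was also higher (17 of 20 positive, median 0.56, and 0.33 without Celf1 AKO replicate 1, 0 adjusted over the list alone, camera adjusted p = 0.000159; 0.416 with an estimated correlation). Its score, too, was higher in Flox control replicate 1 (0.44) than in Celf1 AKO replicate 3 (0.36). Its leading members were Il6 (log2 fold change 2.76), Cxcl2 (4.05), Cxcl12 (0.49) and Ccl3, the last at 0.35 ± 0.084 against 0.16 ± 0.049 CPM.

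Markers of several other cell types differed between the groups. All 9 tested Schwann cell and nerve markers had positive log2 fold changes (median 0.92; 8 higher adjusted over the list alone; camera adjusted p = 5.54e-12; 0.385 with an estimated correlation). Prx, Ngfr and Pmp22 had log2 fold changes of 1.32, 1.56 and 0.67. Endothelial markers were positive for 11 of 12 (median 0.64; 8 higher adjusted over the list alone; camera adjusted p = 9.65e-09; 0.385 with an estimated correlation), among them Kdr (220 ± 24.4 against 138 ± 21.1 CPM), Cldn5 (log2 fold change 1.48), Esam (0.73) and Cdh5 (0.63). Cldn5 passed without Celf1 AKO replicate 3 (edgeR adjusted p = 0.0402). All 8 neutrophil markers were positive (median 2.28, and 0.78 without Celf1 AKO replicate 3; 1 higher adjusted over the list alone; camera adjusted p = 4.78e-06; 0.411 with an estimated correlation). Celf1 AKO replicate 3 was the highest library for these, with S100a9 at 39.4 CPM against 5.22 and 9.59 CPM in the other 2 knockout libraries and S100a8 at 36.1 against 3.53 and 7.11 CPM. Ngp and Csf3r had log2 fold changes of 5.01 and 1.42, the former with 0 counts in 2 control libraries, so that its fitted fold is not a bound.

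Erythrocyte markers were positive for all 6 tested (median 0.87; 0 adjusted over the list alone; camera adjusted p = 0.000195; 0.446 with an estimated correlation), but without Celf1 AKO replicate 3 the median was 0.38 and the camera adjusted p 0.0867. Slc4a1 had a log2 fold change of 1.25, and the haemoglobin genes Hba-a2, Hba-a1 and Hbb-bs, which have near-identical copies and are uncertain one by one, had 0.83, 0.82 and 0.83. Mammary and other epithelial markers were positive for 7 of 8 (median 1.05; 0 adjusted over the list alone; camera adjusted p = 0.0105; 0.678 with an estimated correlation), led by Prlr (0.88, with an edgeR adjusted p of 0.0342 without Celf1 AKO replicate 3), Cdh1 (1.22), Ltf (3.59) and Krt19 (1.47). That list's adjusted p was 0.0727 with limma-voom and quality weights, 0.499 without Celf1 AKO replicate 1, where its median was 0.05, 0.104 without Flox control replicate 1 and 0.0997 without Flox control replicate 3. Eosinophil, ILC2 and mast cell markers were negative for 8 of 9 (median -0.64; 0 adjusted over the list alone; camera adjusted p = 0.0197; 0.678 with an estimated correlation), led by Fcer1a (-1.23), Il1rl1 (-0.74), Cma1 (-0.88) and Tpsb2 (-0.83). Its adjusted p was 0.0883 with limma-voom and quality weights, 0.102 without Celf1 AKO replicate 2, 0.254 without Celf1 AKO replicate 3 and 0.105 without Flox control replicate 3, where its median was -0.28. Its members Siglecf, Epx, Il5, Il13 and Areg were not among the genes analysed. Ccr3, an eosinophil receptor, was at 0.17 CPM in Celf1 AKO and 0.20 CPM in Flox control. The list thus rests mainly on mast cell genes and says little of eosinophils or ILC2.

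**Figure D2:**
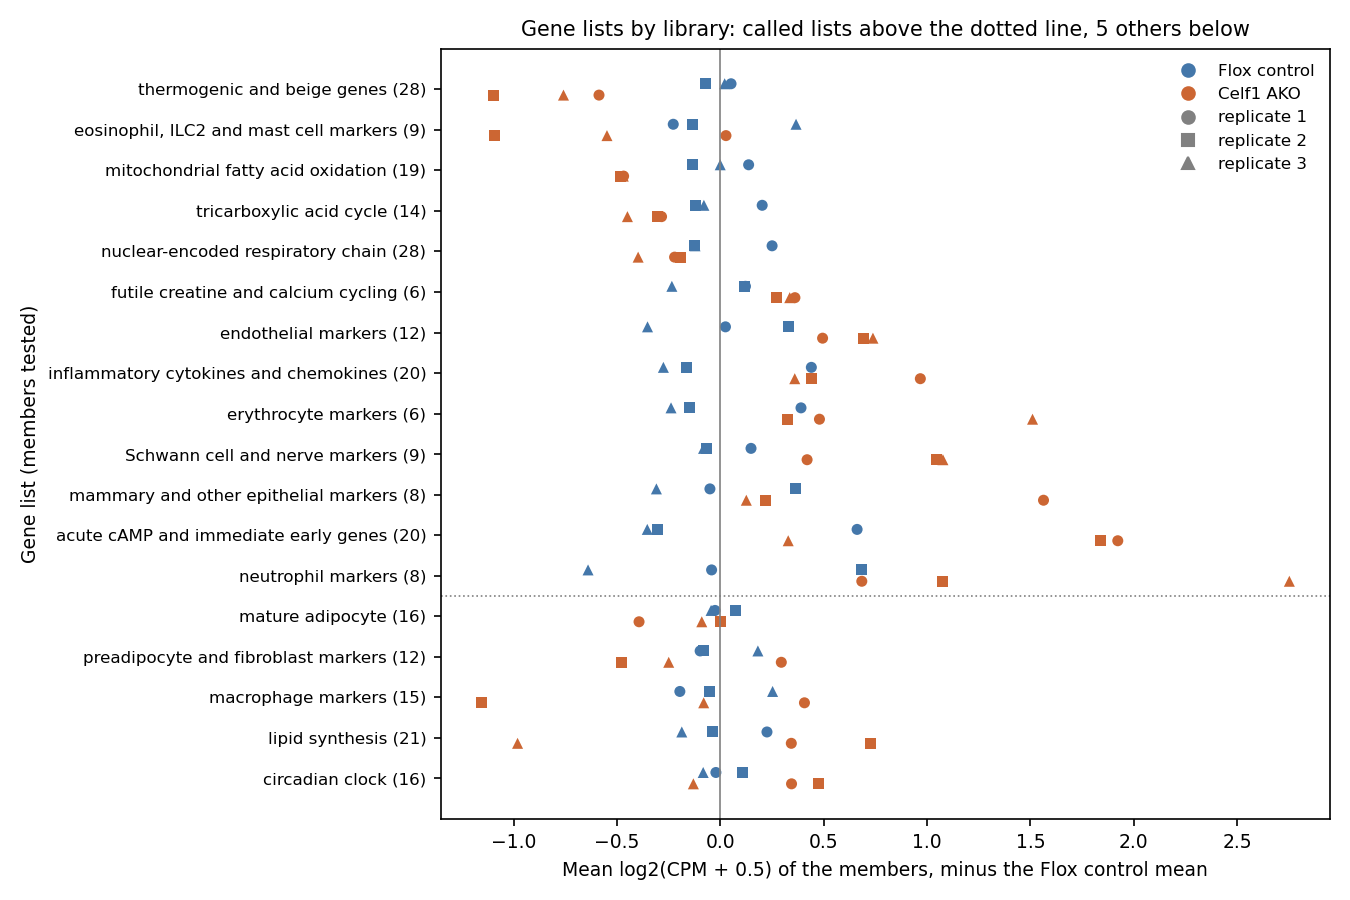
Score of each gene list in each library: the mean log2(CPM + 0.5) of its tested members minus the mean of the 3 Flox control libraries, with Flox control in blue, Celf1 AKO in orange and a symbol per replicate. The thermogenic list lies at -0.59 and -0.76 in Celf1 AKO replicates 1 and 3 and lower still in replicate 2, and the immediate early list at 1.92, 1.84 and 0.33 in Celf1 AKO replicates 1, 2 and 3 and at 0.66 in Flox control replicate 1.

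The mature adipocyte list was not called (16 genes, 11 negative, median -0.05, camera adjusted p = 0.445). Adipoq, the adiponectin gene, was at 2704 ± 102 against 2485 ± 70.8 CPM, and Lep, the leptin gene, at 102 ± 62.2 against 336 ± 216 CPM (edgeR adjusted p = 0.324). Adjusted over the list alone, 3 genes of lipolysis and its adrenergic control were lower and 1 higher, 3 of glucose use lower, 2 heat shock proteins lower and 2 higher, 1 B and T cell marker higher, 1 lipid synthesis gene lower and, among the CELF, MBNL and mRNA decay factors, 1 lower, Celf1. No gene of the lists of circadian clock, macrophage, cholesterol synthesis and uptake, smooth muscle and pericyte, interferon response, preadipocyte and fibroblast, extracellular matrix, integrated stress and unfolded protein response, lipid uptake and handling, control or cell cycle genes passed either way. All these lists and the mitochondrially encoded one had camera adjusted p-values of 0.115 or more, and no member of any of the 35 lists passed over all genes. Median, mean and test differed in sign for the CELF, MBNL and mRNA decay factors, integrated stress, lipid uptake and control lists. The skeletal muscle (3 tested genes), skin keratinocyte (4) and sex-linked (4) lists had no member past the test and were not set tested.

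Leaving out 1 library called lists that all 6 libraries did not. Without Celf1 AKO replicate 3, camera called the circadian clock (adjusted p = 0.000161), lipid synthesis (0.000671) and cholesterol synthesis (0.00220) lists higher. Without Celf1 AKO replicate 1 it called the macrophage (7.84e-06), interferon response (8.02e-05) and preadipocyte (0.000358) lists lower. The B and T cell list was called higher without Celf1 AKO replicate 2 (0.00542) and without Flox control replicate 3 (0.00662), the glucose use list lower without Celf1 AKO replicate 2 (0.0403), and the smooth muscle list higher without Flox control replicate 2 (0.0223).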

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

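Except for the newer edgeR fit and the set test after removing a GC content and length trend, the alternatives were fixed before the data were examined. The count of 2 changed genes came out the same under RLE and upper-quartile normalization, both other filters and the newer fit. It was 0 with library size only, limma-voom, log2(FPKM + 1) and log2(FPKM + 0.1), 1 with log2(FPKM + 1) without a filter, 10 with quality weights, 12 with the replicate block and 497 with DESeq2, and it ran from 0 to 527 when 1 library was left out. The 527 came without Celf1 AKO replicate 3, the library of lowest quality weight (0.356), and the cause of the other differences was not tested. The share of higher genes at an unadjusted p under 0.05 was 52.2% with TMM and 58.0% with RLE, and the median log2 fold change of all genes stayed within 0.05 of 0 under every normalization. Of the 2 genes, both were called in every alternative that called at least 2, except that Gm11868 missed without Celf1 AKO replicate 2 (adjusted p = 0.0571).

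Celf1 was lower under every alternative. It passed with DESeq2 (log2 fold change -1.19), quality weights (-1.25), the replicate block (-1.21) and without Celf1 AKO replicate 3, and leaving out 1 library gave -1.32 to -1.12. The 13 called lists became 0 with an estimated correlation and 0 with fry, and 10 to 15 elsewhere, with no direction reversed; 9 of the 13 stayed called wherever at least 5 of their genes were tested, apart from those 2 tests, and the exceptions are the erythrocyte, epithelial, eosinophil and futile cycling lists. No named gene changed direction. Of the 69 named genes besides Celf1, 35 gained a call with DESeq2, 21 without Celf1 AKO replicate 3, and 5 each with quality weights and the replicate block. Leaving out any other single library gave none of them a new call.

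The replicate numbers were not taken to pair the libraries. Deviations from the group means correlated at 0.07, 0.0017 and 0.30 between same-numbered libraries, and Celf1 AKO replicate 2 correlated best with Flox control replicate 1 (0.31). Besides the 12 genes, the block called 14 lists.

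The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes came from 1 of them, the real one (2 genes; highest of the others, 0). As many lists came from 6 of them (13 lists in the real split; highest of the others, 19). At an unadjusted p under 0.05, the split that sets Celf1 AKO 1 and 2 with Flox control 1 against the rest gave 2806 genes, and the real split 2113. Depth limits genes far below 1 CPM, such as Gm11868 in Flox control (0.14 CPM), which rest on few counts even at 54835348 or more per library.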

Other observations

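The tests below of dilution by muscle, of the table's bounds, of adipocyte share, of the GC content and length trend and of both genomic places were chosen after the result was seen; the test of a second muscle list was not. Ighm, Nr1d1, Per3, Egr1, Acta1, Tnnt1, Tnnc1, Acly, Elovl6, Eif4a2, B630019A10Rik and Cyb5r4 lie outside the rule for named genes and were chosen after their values were seen.

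Immunoglobulin genes, which the rule for named genes skips, were mostly at higher counts in Celf1 AKO. Of 52 tested, 50 had positive log2 fold changes (median 2.83). Their summed level was 324, 586 and 124 CPM in Celf1 AKO replicates 1 to 3 and 110, 38.0 and 54.8 CPM in Flox control, an exact permutation p of 0.1, the smallest possible. Ighm, the constant region of IgM, was at 82.0 ± 28.7 against 27.4 ± 8.67 CPM (SD, n = 3 each; edgeR adjusted p = 0.227). Clock genes went both ways: Nr1d1 was at 291, 242 and 61.4 CPM in the knockout libraries and 65.8, 67.4 and 53.4 CPM in the controls, but Per3 at 13.4, 22.7 and 17.9 against 19.7, 42.6 and 31.5 CPM. The immediate early gene Egr1 was at 375, 302 and 14.8 against 43.1, 10.7 and 7.71 CPM. All libraries were collected after the same stated time in the cold, and hours of collection were not used here.

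Celf1 AKO replicate 3 stood apart from the other 2 knockout libraries, with Acta1, a skeletal muscle actin, at 1039 CPM there and at 23.1 to 75.2 CPM in the other 5 libraries, while genes of fatty acid synthesis were lowest there (Acly at 128 against 2078 and 2559 CPM, Elovl6 at 15.4 against 434 and 717 CPM). A skeletal muscle admixture may account for Acta1. The other 2 tested members of its list were not raised there (Tnnt1 at 0.15 against 0.073 to 0.41 CPM and Tnnc1 at 0.32 against 0.25 to 0.54 CPM in the other 5 libraries). These 2 genes cannot decide it, being under 1 CPM, and only 4 of the list's 16 genes were in the table. The test fixed for the admixture could not be run: 0 of 32 genes on a second muscle list were among the tested genes, and 1 was in the table. The table itself may hide part of the difference, since its largest Cook's distance, a measure of how far 1 library pulls a gene's fit, was 17.9, with 15 genes within 2 below and 0 above the limit of 18 at which DESeq2 withholds a p; 43 of the 72 genes above 10 owed it to this library, whose FPKM factor also exceeded its table total by 0.982%. Dilution of fat RNA by muscle is argued against for the lipid synthesis genes, because mature adipocyte genes lay 1.61 (SE 0.37) log2 units above them against the other 2 knockout libraries. That SE is over the members of the lists in 1 library, and such genes are not independent replicates. No biological explanation of that library, such as feeding state, was tested.

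The same bounds bear on the whole table. Its row order followed the p-values of DESeq2 fitted to all its genes (Spearman's rho 0.998 across genes, which are not independent replicates), no gene lacked such a p, and the smallest mean normalized count was 9.14. A candidate explanation is that it lists the genes to which such a run gave an adjusted p, in line with the largest Cook's distance of 17.9; genes with 1 extreme library would then be missing from all counts above.

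Lower thermogenic and oxidative lists in Celf1 AKO could come from fewer adipocytes in the tissue pieces. For the thermogenic list, medians argue against this as the whole cause. Within a library, the median of its members less that of the mature adipocyte genes differed by -0.55 (SE 0.15) between the groups, and by more than 2 SE with any library left out. Means were tried first, and single genes sway them more. With means, the difference of -0.65 (SE 0.27) came within 2 SE of 0 without Celf1 AKO replicate 2 (-0.43, SE 0.25) or 3 (-0.65, SE 0.46). The argument thus rests on the medians, chosen after the means were seen. For the oxidative lists the difference of medians was -0.23 (SE 0.14). It ran from -0.14 (SE 0.11) without Flox control replicate 1 to -0.33 (SE 0.12) without Celf1 AKO replicate 1. A lower adipocyte share and a lower level per adipocyte thus cannot be told apart there. A lower share would raise all other cell types alike only if their proportions to each other stayed fixed, which was not tested. The endothelial and Schwann lists moved apart from the preadipocyte, macrophage and eosinophil lists by 1.06 (SE 0.55) with medians and 1.06 (SE 0.52) with means. With medians this was 0.69 (SE 0.59) without Celf1 AKO replicate 2 and 1.51 (SE 0.41) without Celf1 AKO replicate 1. Fewer beige cells among the adipocytes were not tested for either the thermogenic or the oxidative lists. A trend with GC content or transcript length is argued against as the whole cause: it held 1.20% of the variance of the statistic, and in each of the 4 lists it held at most 3.98% of the shift. In camera's test of the ranked statistic, 11 of the 13 called lists were called after removal of the trend. The eosinophil and futile cycling lists were not (adjusted p of 0.0761 and 0.104), nor were they before its removal (0.0503 and 0.0835). Genotype stays open as the biological explanation.

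Some of the differences may lie at 2 genomic places. Every library came from a mouse kept in the cold, so no difference here can be assigned to the response to the cold. Within 200 kb of Adipoq on chromosome 16, 7 of the 8 other tested genes had positive log2 fold changes, with a median of 0.59, higher than in 99.3% of windows of as many genes; Eif4a2 was at 618 ± 38.5 against 371 ± 26.7 CPM (edgeR adjusted p = 0.215) and B630019A10Rik at 0.98 ± 0.31 against 0.16 ± 0.095 CPM (0.227); 3 of the 8 had an unadjusted p under 0.05 and 0 passed. A candidate explanation is a Cre transgene that carries extra copies of the Adipoq neighbourhood; the labels do not name the driver, and some of these genes overlap. The other place is chromosome 9: Zfp949 lies 1.47 Mb from Cyb5r4, the gene that Gm11868 copies, and Cyb5r4 was at 29.3 ± 2.63 against 40.6 ± 2.91 CPM (log2 fold change -0.47). A chromosome 9 haplotype that differs between the groups, with variant Cyb5r4 reads assigned to the pseudogene, would tie both called genes together. Within 2 Mb of Zfp949, 7 of 32 genes had an unadjusted edgeR p under 0.05, which exceeded only 88.1% of windows of as many genes. Zfp949 and Cyb5r4, which drew attention to this window, are among the 7 and raise that share. The comparison thus decides nothing.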
